A study of Homo sapiens with 28 samples.

How the data were processed

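Genomic DNA of K562 cells, an established human chronic myeloid leukaemia line, was measured after transduction with pooled synthetic introns. The cells carried either wild-type SF3B1 (WT) or the SF3B1 K700E change, a recurrent cancer mutation in a splicing factor that takes part in branch point recognition. Introns were amplified with primers specific for TK, per the labels' protocols. Thymidine kinase (TK) turns ganciclovir into a toxic product, so cells with functional TK are lost under the drug. The large library had 24 labelled sequencing runs, and the pilot library had 4.

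The deposited tables hold read counts per intron, made by the authors with cutadapt and Bowtie2, per the submitters' processing notes. Tool versions and alignment settings are not given in the sources used here. Blank cells of the large table, 1404 in number, were read as counts of 0, because the lowest written value was 1. A further 13 columns of per-sample counts matched no labelled sample and were not used here. By their names, 12 of these hold untreated cells at day 8, which would bear on whether time or ganciclovir changed an intron. The remaining column has the same total as the 250 bp run of WT day 8 replicate 1, and the pair was not compared further. The titles of the 4 pilot samples name the cells K662 while their cell line label says K562, which was used here. The title and the description of the WT ganciclovir pilot library carry different letter codes, and its group was taken from the words of the title. All counts in the pilot table were even, so both mates of a pair may have been counted, and its intervals would then be too narrow.

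By title, each replicate number of a genotype and day in the large library had a run of 150 bp reads and a run of 250 bp reads. Both runs with the same number were taken as 1 sample and summed into 1 unit, which gave 12 units, 3 per genotype and day. The rule for summing was met, since 97.3% of the introns that passed the filter in either read length passed it in both. The labels do not say how the runs relate. Deviations of the runs from the mean over all units of that read length correlated with r of 0.928 to 0.97 within a unit. With any other unit r was at most 0.335. Unit totals ranged from 2509230 to 6243439 reads, with medians of 226 to 602 reads per intron. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. No labelled sample of the large library was untreated at day 8, so time in culture and ganciclovir were not separated here. The third replicates stood apart in all 4 groups. Their ratio of 250 bp to 150 bp reads was 1.336 to 1.39, against 0.782 to 0.827 in the others, a difference treated here as a sequencing batch, which the labels do not name. Each group holds 1 such unit, and a batch term, values within each batch and regrouping within batches were added after the data had been seen.

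Counts were fitted with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, 1 coefficient per genotype and day) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 8878 introns, 8853 passed the filter. Families of at least 10 introns were defined by design module, length, and region of substitution, and 96 families were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. The rule for families, the edgeR and camera tests, the rule for named introns and the first set of alternatives were fixed before the data were examined. Named introns were the 3 most negative and 3 most positive past the threshold in each comparison. For the difference between genotypes the rule took introns past the threshold with separate replicates, plus any unmodified parent intron that was marked, and all pilot introns and marked controls. Alternatives covered scaling, filtering, DESeq2 1.42.0, single read lengths, a replicate block, fits of only the groups compared, a log2 minimum of 1, and leaving out each unit.

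On simulated counts, the test of the difference recovered 4% of introns changed by 1 on the log2 scale and 43% of those changed by 2. For the change in K700E these shares were 9% and 88%. For the comparison at day 8 they were 14% and 77%. The fits made 2 or 3 false calls among 8650 unchanged introns.

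Intron IDs give the parent, module, kind of change, position from 0 at the 5' end, and length. All introns derive from MTERFD3, an older symbol of MTERF2, matched in the RefSeq table of GRCh38.p14. No genome build is given in the sources used here, so no coordinates are printed. Sequences of the 150 nt and 100 nt parents were rebuilt from the reference bases in the single-substitution IDs. The kinds of region were part of the rule for families, but their boundaries in the 150 nt intron were drawn from that sequence after the position profile had been seen, so the region families are not free of that choice. The classes of double substitution were drawn at the same point. They were the 5' splice site at positions 0 to 5, the body at 6 to 91, a pyrimidine-rich part at 92 to 118, a branch point region at 119 to 127, and the stretch before the upstream AG at 128 to 137. The upstream AG lay at 138 to 139, followed by the stretch between the AGs at 140 to 146 and the terminal CAG at 147 to 149.

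Region scores were added after the data had been seen. In each unit the score was the median over a set's introns of log2(count + 0.5), minus the median of the control introns without splice sites at that length. Controls with a mean of at least 50 reads and introns with a mean of at least 10 reads entered. Lengths other than 100 and 150 nt were set on a line through both groups of controls. Scaling to the sum of the controls was tried first and dropped, because intron_13612 alone took up to 1.867% of a unit's reads. The change is the mean at day 8 minus the mean at day 0, with its SE from 3 units per day. Differences between genotypes were tested with a two-sided exact permutation of genotype within each day, over 400 regroupings, whose smallest possible p is 0.005. In simulated scores this test passed the threshold in 3.8% of sets without a difference and in 50.6% of sets with a difference of -0.8, so it missed many real differences. Both days are regrouped independently. Where the units separate fully at day 8, p thus depends mainly on the genotype gap at day 0, and a larger difference need not lower it. Values were adjusted separately over 22 sets of regions and double substitutions, 52 modules (within batches 50, without the controls), and 9 sets of deletions and replacements. Over 22 sets or 52 modules, a lone set at the smallest possible p could not pass the threshold.

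Pilot shares carry exact (Clopper-Pearson) 95% intervals. These amplicon reads carry no molecular identifiers, so the intervals cover counting error only. Scores and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.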

Results

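The series measured how synthetic introns placed in a TK gene behaved in SF3B1 K700E and WT K562 cells. In the large library, 8878 introns were counted at day 0 and after ganciclovir at day 8, with 3 units per genotype and day. In the pilot library, 8 introns were counted at day 6 with and without ganciclovir at 100 ug/mL, with 1 library per condition. Unit totals of the large library ran from 3542175 to 4484607 reads in K700E at day 0 and from 2509230 to 5813597 in K700E at day 8. In WT they ran from 3685249 to 3784951 at day 0 and from 2917903 to 6243439 at day 8. Positions in an intron are counted from 0 at its 5' end. The common biological coefficient of variation between units was 0.357.

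The first question was whether the change of an intron from day 0 to day 8 differed between K700E and WT. No single intron passed the threshold for this difference in the edgeR quasi-likelihood test, with 1069 of 8853 introns at an unadjusted p under 0.05. DESeq2 called 115 introns, 110 of them lower in K700E relative to WT. As a group, single substitutions of the 150 nt intron had a median log2 difference of -0.88 over 439 introns. Their median change was -0.83 in K700E and, in WT, 0.07 under TMM scaling, which turned to -0.14 relative to the 150 nt controls. Single substitutions of the 100 nt intron had a median difference of 0.23, over 294 introns, under TMM scaling. That sign turned when each unit was set against control introns of 100 nt, which gave -0.24 ± 0.07 (SE, 3 units per genotype and day).

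Families were tested for the same difference. Camera with the preset correlation called 66 of 96 families, 36 of them lower in K700E, and no family was called with an estimated correlation. The 150 nt single substitutions had an adjusted p of 1.05e-22 with the preset correlation and adjusted p = 0.179 with an estimated correlation. Regrouping the units called up to 82 families, so the count of 66 did not exceed what other groupings gave. Median differences by intron length were 1.19 at 75 nt (57 introns), 0.33 at 100 nt (1416 introns), -0.75 at 145 nt (97 introns) and -0.36 at 150 nt (3665 introns). The order was not strict, since 110 nt, 118 nt and 126 nt stood at 0.40, 0.34 and 0.32 and 115 nt and 120 nt at -0.13 and -0.26. The control introns of 100 nt and 150 nt stood at 0.46 and -0.18. Under TMM the 150 nt controls themselves shifted by 0.01 in K700E and 0.21 in WT, and the 100 nt controls by 0.49 and 0.02.

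The position profile gave this difference by substituted position. No ID of the large library marks an unmodified 150 nt parent, so a median below 0 need not be an effect of the substitution. Intron_26 (25to125, 150 nt), whose ID names a deletion and no substitution, may be that parent, which was not checked. Relative to the 150 nt controls it stood at -0.87 ± 0.20 in K700E and -0.12 ± 0.10 in WT (SE, n = 3 units per day). A fall in K700E was thus also seen in an intron without a listed substitution. Substitutions in the body of the 150 nt intron had a median difference of -0.95 over 251 introns, and those in the pyrimidine-rich part had -1.04 over 81 introns. Before the upstream AG the median was -0.90 over 29 introns, in the branch point region -0.63 over 26, and between the AGs -0.53 over 20. In 150 nt introns scaled to their controls, the branch point region and the stretch between the AGs shrank to -0.40 and -0.32. At the 5' splice site it was -0.06 over 18 introns, and this sign turned to 0.20 when the fit was restricted to 150 nt introns and scaled to the controls.

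Set against the 150 nt controls in scores added after the profile had been seen, body substitutions had a change of -0.95 ± 0.09 in K700E (SE, n = 3 units per day) and -0.13 ± 0.09 in WT, where the median under TMM had the opposite sign at 0.08. A score of that size in K700E corresponds to 0.519 of the starting level. Minus the day 0 mean of their genotype, all 3 K700E units at day 8 lay below all 3 WT units. The difference between genotypes was -0.97 within the first and second replicates and -0.52 within the third, which stood apart in their ratio of 250 bp to 150 bp reads. Substitutions before the upstream AG had values of -0.95 ± 0.06 in K700E and -0.07 ± 0.08 in WT, against 0.03 in WT under TMM. At the 5' splice site, the junction at the start of an intron, the values were 0.15 ± 0.16 in K700E and -0.20 ± 0.07 in WT, against 0.06 in WT under TMM. At the terminal CAG, which ends the intron, they were 0.11 ± 0.36 and -0.25 ± 0.14 over 9 introns, and the WT value turned to 0.03 with library totals. The K700E value there turned to -0.06 with the 150 bp runs. It was -0.12 without K700E day 0 replicate 2 and -0.10 without K700E day 8 replicate 3. None of the 22 sets passed the exact permutation test (two-sided, smallest possible p of 0.005) after adjustment, and the body had an unadjusted p of 0.1 and an adjusted p of 0.33. A lone set at that smallest p could not pass over 22 sets, so the lack of calls does not argue against a difference. The body separated fully at day 8, and its p then depended mainly on the day 0 gap, not on the size of the difference. That gap was -0.15, in the direction of the difference, which kept p far above its smallest value. The lowest unadjusted p was 0.015, for double substitutions at the upstream AG, with the same adjusted p of 0.33. For these the unadjusted exact permutation p rose to 0.425 with library totals and to 0.28 with the sum of the controls. Permuted within day and batch, the body had an exact p of 0.167 and these double substitutions 0.0278, with 0.437 for both after adjustment. The smallest possible p of that permutation was 0.0139.

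**Figure D1:**
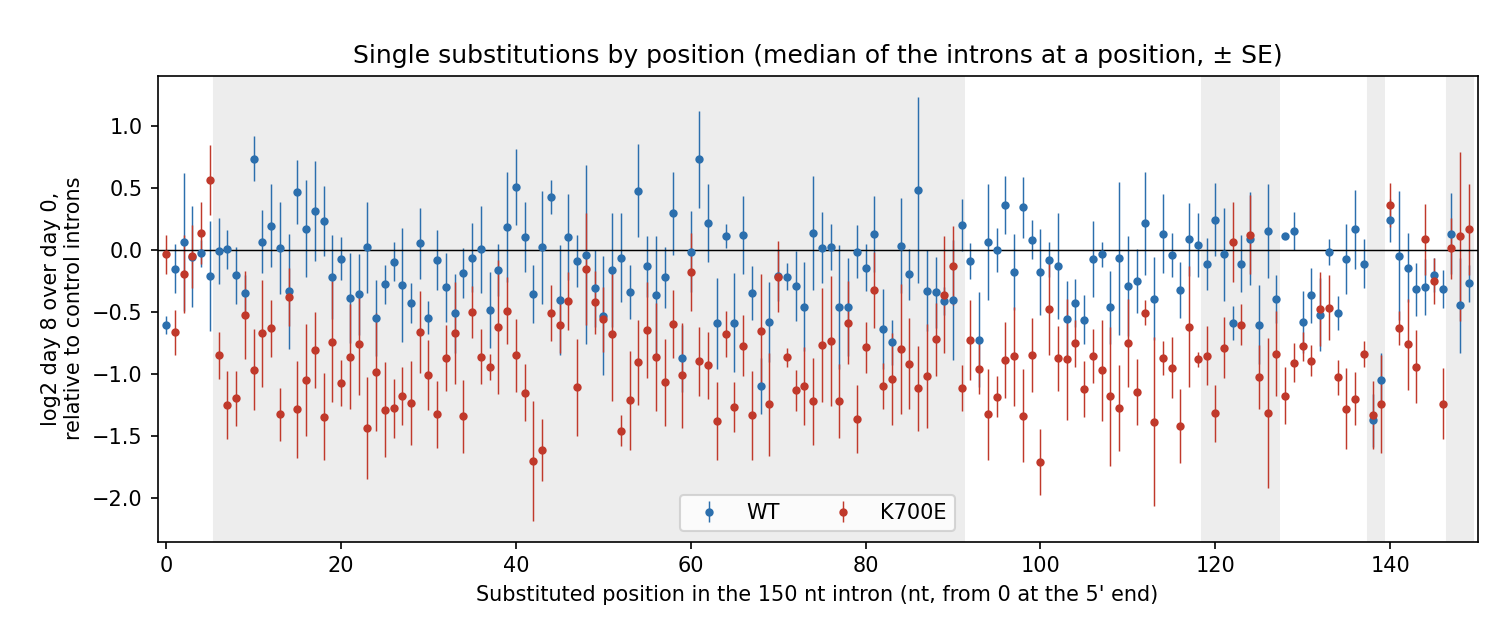
The plot gives, for each substituted position of the 150 nt intron (x axis, nt from 0), the log2 change from day 0 to day 8 relative to control introns (y axis), with K700E in red, WT in blue, bars for the SE, and shading for alternate regions. At position 124 the change was 0.13 in K700E and 0.09 in WT, while at position 138 it was -1.33 and -1.37.

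**Figure D2:**
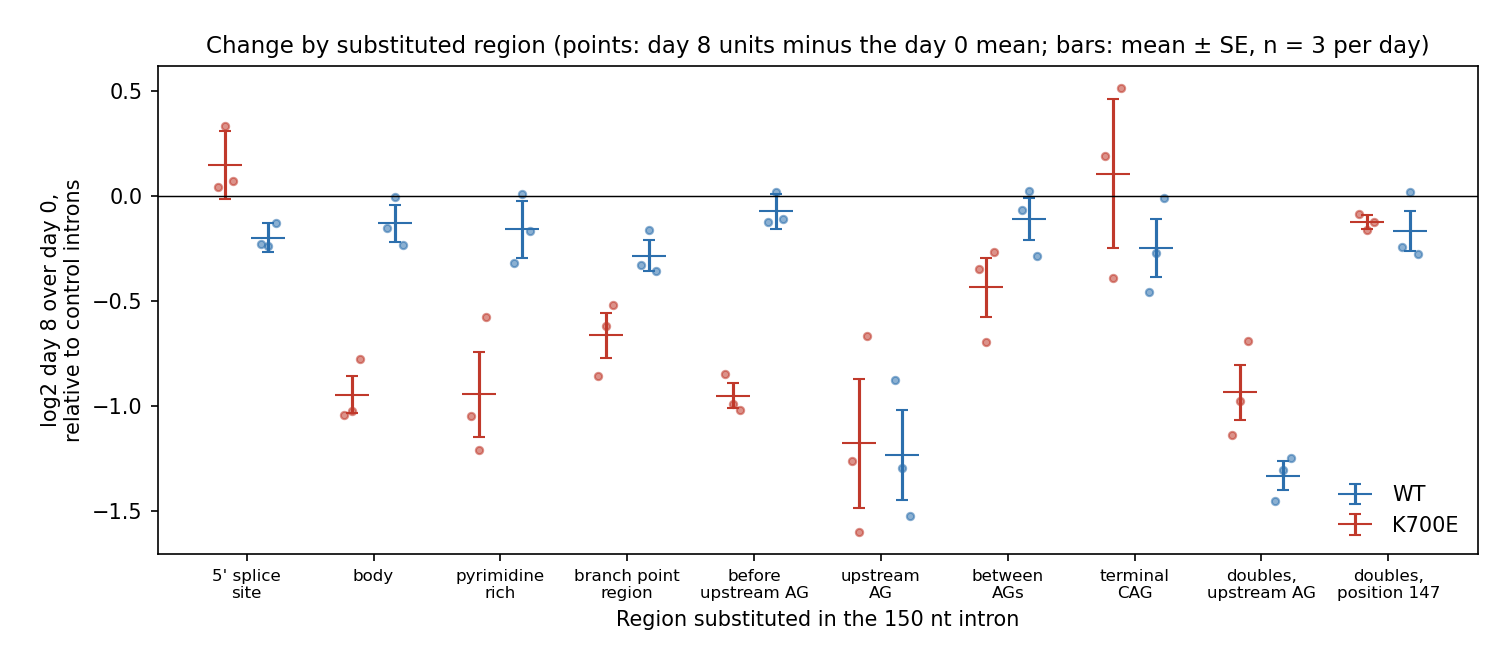
The plot gives the log2 change relative to control introns (y axis) by substituted region (x axis), with points for the 3 day 8 units minus the day 0 mean, and bars for the mean and SE. Body substitutions lay at -0.95 in K700E and -0.13 in WT, and double substitutions at the upstream AG lay at -0.94 and -1.33.

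In K700E, 151 introns changed from day 0 to day 8 under ganciclovir, of which 143 fell and 8 rose (edgeR quasi-likelihood test). Of the introns that fell, 118 were 150 nt long, 67 were double substitutions near the 3' end and 26 were single substitutions of the 150 nt intron. This make-up by length depended on TMM scaling, under which 0 introns of 100 nt were called lower. In a fit of 100 nt introns scaled to their own controls, 103 fell and 1 rose in K700E. Under TMM, single substitutions of the 150 nt intron were over-represented among them (Fisher's exact test, adjusted p = 1.01e-07). Fisher's tests here and for WT treat introns as independent although all share the same units, so their p-values do not measure replication. The largest fall was in intron_7401 (136_CtoT-146_GtoA), from 44.9 ± 14.4 to 3.88 ± 2.62 CPM (SD, n = 3), followed by intron_6065 (128_GtoC-129_CtoG) and intron_6644 (131_AtoT-137_AtoG) with log2 changes of -3.17 and -2.64. Their edgeR adjusted p-values were 0.0355, 0.0272 and 0.0217. The largest rises were in intron_2011, intron_3199 and intron_3106, which hold repeats of TACTAACA, the branch point motif of yeast, with log2 changes of 2.99, 2.25 and 2.23. Introns of this repeat module were scarce, with a median of 36.0 CPM against 99.3 CPM over all introns. No control intron was called. The count rested on few libraries: it was 0 without K700E day 0 replicate 3, 38 without K700E day 8 replicate 1, 49 without K700E day 8 replicate 2 and 77 without K700E day 0 replicate 2. It was also 0 when only both K700E groups were fitted, 3 with the first and second replicates alone, 38 with the 250 bp runs, 49 without TMM and 701 with DESeq2.

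In WT, 57 introns changed from day 0 to day 8, of which 54 fell and 3 rose. Double substitutions at the upstream AG made up 29 of the 54, more than their share of the library (Fisher's exact test, adjusted p = 1.95e-26), and no single substitution of the 150 nt intron was among them. Relative to controls this class of 315 introns had a change of -1.33 ± 0.07 in WT and -0.94 ± 0.13 in K700E (SE, n = 3 units per day). Deletions that reached the upstream AG but not the branch point region or terminal CAG had values of -1.31 ± 0.14 in WT and -1.12 ± 0.20 in K700E over 16 introns. The introns with the largest falls were intron_8777 (141_2xGTATTT), intron_2555 (33_4xTACTAACA) and intron_7330 (136_CtoT-138_AtoC), with log2 changes of -4.56, -3.21 and -3.02. Intron_7330 fell from 93.1 ± 37.3 to 11.6 ± 3.81 CPM (SD, n = 3). The others were scarce and ended near the floor. Intron_8777 went from 16.3 ± 2.58 to 0.667 ± 0.189 CPM and intron_2555 from 15.2 ± 8.90 to 1.65 ± 0.431 CPM. The introns that rose were intron_2447, intron_7475 and intron_5659, with log2 changes of 2.91, 2.01 and 1.94. No control intron was called. Introns that fell in both genotypes numbered 7, against 0.87 for independent lists (Fisher's exact test, p = 2.33e-05). The count fell to 0 without WT day 0 replicate 2 or WT day 8 replicate 2, to 1 without WT day 8 replicate 1, to 11, 26 and 30 without WT day 0 replicate 3, WT day 0 replicate 1 and WT day 8 replicate 3, and to 34 without K700E day 0 replicate 1 or with the 250 bp runs. DESeq2 called 256, and the first and second replicates alone gave 1.

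At day 8, 28 introns differed between K700E and WT under TMM scaling, 16 lower and 12 higher in K700E. This balance depended on the scaling, since 150 nt introns scaled to their controls gave 224 lower and 13 higher, 100 nt introns 144 and 2, and a length trend set by the controls 370 and 23. The lowest were intron_6065, intron_6852 (132_TtoC-143_AtoT) and intron_6644, with log2 differences of -3.07, -2.44 and -2.41. Intron_6852 stood at 26.8 ± 15.4 CPM in K700E and 144.2 ± 22.6 CPM in WT (SD, n = 3). The highest were intron_2555, intron_13586 and intron_8287 (140_TACTAACA), with log2 differences of 4.13, 2.90 and 2.39. Intron_2555 stood at 29.0 ± 19.2 CPM in K700E and, near the floor, at 1.65 ± 0.431 CPM in WT. Intron_13586 is a control without splice sites, at 144.1 ± 73.7 CPM in K700E and 19.4 ± 7.78 CPM in WT, so 1 of 100 controls of that length was called. The count was 0 without any 1 of the 3 WT day 8 units, 7 without K700E day 8 replicate 1 and 18 without K700E day 0 replicate 3. It was 0 when only both groups at day 8 were fitted, 1 with the first and second replicates alone, 15 with the 250 bp runs and 295 with DESeq2.

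At day 0, no intron differed between K700E and WT in the edgeR test, with 880 at an unadjusted p under 0.05, while DESeq2 called 27, all higher in K700E. Medians by length ran from -0.81 at 75 nt to 0.60 at 168 nt, with 0.34 at 150 nt. Control introns showed the same imbalance between units: the ratio of the 150 nt to the 100 nt control median was 1.437 in K700E replicate 3 and 0.414 in WT replicate 3. In the other day 0 units it was 0.820 and 0.954 for K700E and 0.779 and 0.789 for WT.

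The pilot library set ganciclovir against no drug at day 6, with totals of 3329210 to 4048134 reads. With 1 library per condition no test was possible. The share of intron_26 (25to125, 150 nt) went from 22.98% (95% interval 22.94 to 23.02) to 14.83% (14.79 to 14.86) in K700E, a ratio of 0.645, against a ratio of 1.035 in WT. The original 250 nt intron had ratios of 0.526 and 0.961, intron_9600 with TACTAACA inserted at position 89 had 0.539 and 1.114, and intron_8499 with 4 A-to-G changes had 0.633 and 1.151. The control intron_13121 without splice sites had 2.05 in K700E and 1.227 in WT, and intron_2790 (148_AtoG) had 1.741 and 1.044, whose K700E over WT ratio of 1.668 turned to 0.998 relative to that control. Relative to it, the WT ratios of intron_9600, intron_8499 and intron_26 became 0.908, 0.938 and 0.844. Their K700E over WT ratios went from 0.484, 0.55 and 0.623 to 0.29, 0.329 and 0.373. Intron_4095, with both bases of the upstream AG changed, had 0.603 in K700E and 0.331 in WT, the lowest WT ratio of the 8. Relative to the control intron these became 0.294 and 0.27, so that the K700E over WT ratio of 1.823 shrank to 1.091. The 100 nt intron_2258 had 1.143 and 1.28. Its K700E over WT ratio of 0.893 turned to 1.272 when shares were taken relative to the median intron, while it was 0.534 relative to the control intron and 0.799 without the most abundant intron. The large library compares day 8 with day 0 instead. Relative to controls, intron_26 differed between genotypes there by -0.75 ± 0.23 on the log2 scale (SE). Introns with the listed change of intron_9600 differed by -0.17 ± 0.49 and 0.21 ± 0.82, and that of intron_2790 by 0.09 ± 0.75. The intron_4095 change stood at -0.64 ± 0.52 in WT and -0.15 ± 0.70 in K700E. Apart from intron_26, these SEs are too wide to tell whether the pilot pattern recurred.

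**Figure D3:**
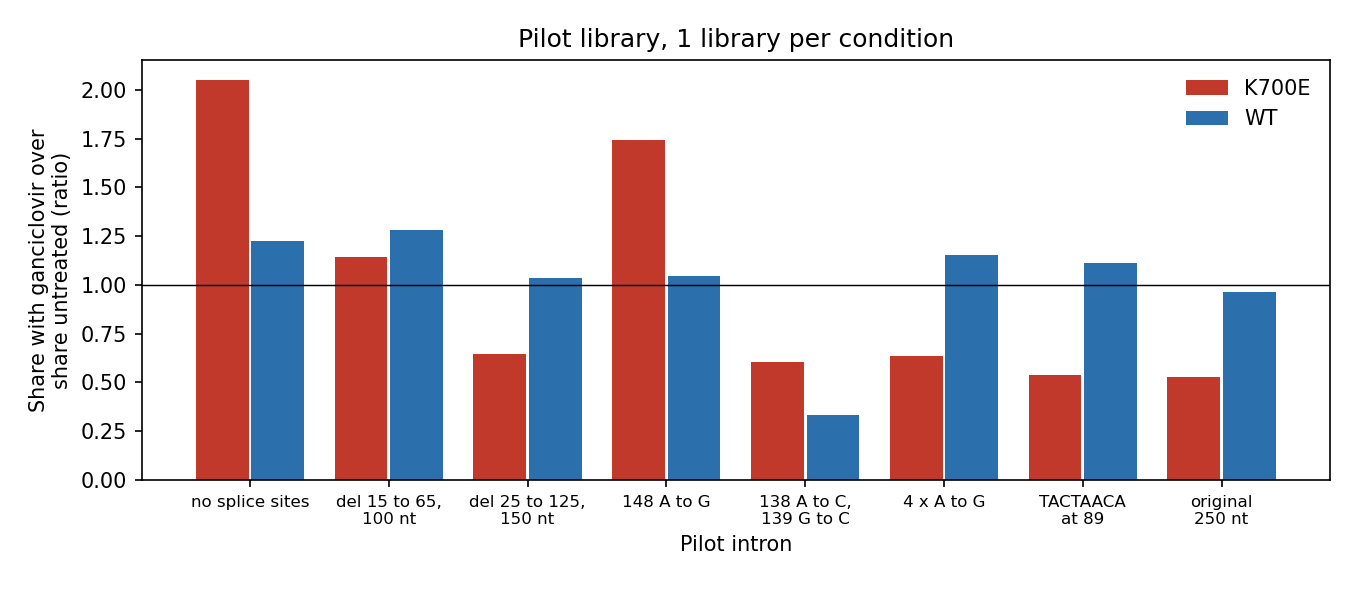
The bars give the share of reads with ganciclovir over the share without it (y axis, ratio from 0) for each of the 8 pilot introns (x axis) in K700E (red) and WT (blue), with 1 library per condition and a line at 1. The control without splice sites stood at 2.05 in K700E, and the original 250 nt intron stood at 0.526 in K700E and 0.961 in WT.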

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

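The tests in this part other than the planned family test, the regrouping of units included, were chosen after the results had been seen. In the planned family test of the difference between genotypes, 66 of 96 families were called with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.179. Of 60 groupings of the units, 17 called as many families, and the highest other called 82, so chance was not excluded for that count, nor was it within batches, where 30 of 72 groupings called as many and the highest other called 82. For the difference of single introns, all 60 groupings, and all 72 within batches, gave at least the real count of 0, and the highest others gave 1 and 4. For introns at an unadjusted p under 0.05, a count examined after the fact, 1 of 60 groupings, the real one, reached 1069, and the highest other gave 981. With a batch term and regrouping within batches, 4 of 72 groupings reached the real 1095, and the highest other gave 1198, so chance was not excluded once the batch was kept. For the changes in K700E and WT and the comparisons at day 8 and day 0, the 10 splits are too few for a share under 0.05. The real counts were 151, 57, 28 and 0, the highest others were 0, 0, 2 and 0, and 1, 1, 1 and 10 splits were as large.

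Within 150 nt introns scaled to their controls, 3 overlapping families differed between genotypes with an estimated correlation. The medians of the difference were -0.68 for all single substitutions (camera adjusted p = 0.0158), -0.78 for those in the body (0.0154) and -0.67 for those before the upstream AG (0.0154). The same families had adjusted p = 0.179 in the planned fit of all introns. Of 60 groupings, 2 called at least as many families as the real 3, and the highest other called 6. With a batch term and regrouping within batches, 10 of 72 called at least as many as the real 5, and the highest other called 10, so chance was not excluded. The boundaries of the region families were also drawn after the real profile had been seen. Substitutions at the 5' splice site lay above the day 0 mean in all 3 K700E units and below it in all 3 WT units, a difference of 0.35 on the log2 scale, with an exact permutation p of 0.105 and an adjusted p of 0.33. At day 0 this set already differed between K700E and WT by -0.34, about the size of that difference, and the WT change turned to 0.08 with library totals and 0.12 with the sum of the controls, so the opposite directions were lost. Against day 0 of their own batch, the third replicates stood at -0.11 in K700E and -0.19 in WT, so they did not show opposite directions either. The 9 introns of module mod19a, with changes at regular spacing, also lay above the day 0 mean in all 3 K700E units and below it in all 3 WT units, with a difference of 0.53, an exact permutation p of 0.015, an adjusted p of 0.318 and a difference of -0.41 already at day 0. Within batches, mod19a stood at 0.07 in K700E and -0.42 in WT in the first and second replicates and at 0.41 and -0.20 in the third, with an exact permutation p of 0.0278 and an adjusted p of 0.424.

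The lower level of body substitutions in K700E at day 8 was weighed against technical causes. Recovery by intron length would leave no difference against controls of the same length, where it was -0.82 ± 0.13 (SE). A shift of the controls themselves would leave none against introns with double substitutions at the 5' splice site, where it was -0.93 ± 0.13. Leaving out each library in turn brought it no closer to 0 than -0.75. The exact permutation of SF3B1 genotype within day gave p = 0.1, and 0.01 with library totals (adjusted p = 0.055) and 0.05 with the sum of the controls (adjusted p = 0.367), so genotype and chance cannot be told apart by that test, and time in culture was not separated from ganciclovir, since the columns named as untreated at day 8 were not used here.

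Double substitutions at the upstream AG were over-represented among the introns that fell in each genotype. Low counts do not account for this, since the median count at day 0 in WT was 373 per intron and unit. Recovery by length was argued against by a WT change of -1.33 relative to controls of the same length. A candidate explanation is the loss of that AG itself: among triple and quadruple A-to-G introns, those that include position 138 lay lower in WT by -0.36 ± 0.06 (SE) than those that do not, over 84 and 126 introns. In K700E they lay lower by -0.19 ± 0.07. These gaps are between introns with several substitutions. Their size does not compare with the -1.33 and -0.94 of the double substitutions, which were set against controls. Against controls, single substitutions of that AG stood at -1.23 ± 0.21 in WT and -1.18 ± 0.31 in K700E over 5 introns. Those before it and between the AGs stood at -0.07 and -0.11 in WT and at -0.95 and -0.44 in K700E. Among these single substitutions the WT fall went with that AG and not with its neighbours, in the same samples that gave the explanation. Hexamer repeats inserted after that AG also fell in WT, to -1.18 ± 0.10, while those inserted before the branch point region stood at 0.02 ± 0.16. TACTAACA replacements in the branch point region stood at -0.68 ± 0.16 in WT, and deletions that reached it at -0.20 ± 0.06. A fall in WT was thus also seen with that AG kept, so its loss stays a candidate only. In K700E substitutions before that AG fell about as far, so the explanation stays open there.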

How the results depend on the processing

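Settings that scale to control introns, restrict to 1 length, use the robust fit or treat the third replicates as a batch, and all region scores, were chosen after seeing the data; the causes of the moves were not tested. DESeq2 called 115 introns for the difference, 701 for K700E, 256 for WT, 295 at day 8 and 27 at day 0. Fits of only the groups compared gave 0 for K700E and 0 at day 8. The 250 bp runs alone gave 38, 34 and 15 for K700E, WT and day 8, and K700E without TMM gave 49. The first and second replicates alone gave 3, 1 and 1, with fewer samples, and a batch term gave 143, 67 and 23. In 150 nt introns scaled to controls the counts were 319, 126 and 237, and with a length trend set by controls 540, 197 and 393. In 100 nt introns scaled to controls, where fewer introns were tested, they were 104 for K700E, 22 for WT, 146 at day 8, 1 for the difference and 1 at day 0. Of the 104 for K700E, 103 were lower, and 0 were among the 151 of the main fit.

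Leaving out 1 unit gave 0 to 209 introns for K700E, 0 to 65 for WT, 0 to 35 at day 8, 0 to 3 for the difference, 0 at day 0, and 54 to 74 families. With an estimated correlation 0 families were called, and 2 with library totals in place of TMM. The replicate block gave 123 introns for K700E, 58 for WT, 0 for the difference and 66 families. Replicate numbers were not taken to pair the samples, since not every pair's day 0 and day 8 deviations correlated above 0.1: r was 0.025, 0.061 and 0.124 in K700E and -0.026, 0.174 and 0.154 in WT. Replicate 1 of each genotype correlated better with another number, the others best with their own.

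The difference at the upstream AG, from 5 single substitutions, reversed to -0.244 with the 150 bp runs, -0.086 with library totals and -0.067 with the sum of the controls, and ranged from -0.199 to 0.268 without 1 unit. The differences between genotypes of the other 150 nt regions and of double substitutions at the upstream AG kept their direction under these settings, and none passed the threshold. The WT change itself turned with library totals, to 0.15 in the body, 0.12 in the pyrimidine-rich part, 0.21 before the upstream AG, 0.17 between the AGs and 0.03 at the terminal CAG. In the pilot, intron_2258 reversed to 1.272 relative to the median intron and intron_2790 to 0.998 relative to the control. The number of pilot introns with a lower ratio in K700E than in WT was 5 of 8, and 4 to 6 under the alternatives.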

Other observations

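All tests in this part were chosen after the data had been seen. Deletions outside the splice sites, the branch point region and the upstream AG had a change of -0.69 ± 0.07 in K700E and -0.09 ± 0.05 in WT (SE, n = 3 units per day) over 589 introns, relative to controls. Deletions that reached the 5' splice site stood at -0.11 ± 0.08 and 0.02 ± 0.06 over 38 introns, and those that reached the terminal CAG at -0.27 ± 0.07 and -0.25 ± 0.10 over 24 introns. Hexamer repeats inserted at position 118 had values of -0.82 ± 0.29 in K700E and 0.02 ± 0.16 in WT, and those inserted at position 141, after the upstream AG, had -0.79 ± 0.27 and -1.18 ± 0.10, over 36 introns each. None of these differences between genotypes passed the exact permutation test after adjustment.

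A hypothesis was that position 124, the position of the branch point region with the highest K700E value among single substitutions, is needed for the lower level in K700E. Among triple and quadruple A-to-G introns with position 138 intact, 56 change position 124 and 70 do not. Those that change it lay higher in K700E by 0.63 ± 0.06 (SE), and by 0.18 ± 0.05 in WT. That goes with the hypothesis, though other introns of the same samples were used to form it. Relative to controls, deletions that reached the branch point region still stood at -0.46 ± 0.06 in K700E and -0.20 ± 0.06 in WT, over 154 introns. TACTAACA replacements there stood at -1.07 ± 0.22 in K700E and -0.68 ± 0.16 in WT, over 16 introns. These need not all change position 124, and TACTAACA is itself a branch point motif, so the hypothesis stays open. A second hypothesis was that the same positions matter in the 100 nt intron. Across 85 shared positions, which are not independent replicates, the genotype differences of both parents correlated with Pearson's r of 0.059 (permutation p = 0.6) and Spearman's rho of 0.038 (permutation p = 0.7). The predicted correlation was thus not seen. With 2 or 3 introns per position of the 150 nt parent, and an SE of 0.45 at position 139, that cannot refute the hypothesis. It also covers genotype differences only. Relative to controls, substitutions of the upstream AG stood low in both parents. They had -1.18 in K700E and -1.23 in WT at 150 nt, and -0.80 ± 0.18 and -0.89 ± 0.11 at 100 nt.

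The module of paired A-to-G changes (mod5a, 36 introns) varied widely between units, with scores relative to controls of 2.91 in K700E day 8 replicate 3 and 0.46 in K700E day 8 replicate 1, and its difference between genotypes was 0.83 ± 0.82 (SE).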
